A study of Mus musculus with 12 samples.

How the data were processed

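Gene expression was measured in the proximal jejunum of 12 mice, each hybridised to 1 Affymetrix array, per the series design text. There were 4 groups of 3 mice: wild type or TLR2 knockout, each left untreated or given methotrexate. Total RNA was cleaned with a DNase step and converted to labelled cDNA with a whole-transcript kit, per the labels' protocols. The authors deposited log2 signal values per probe set made with RMA (robust multi-array average, which corrects background, normalises between arrays and summarises probes), per the submitters' processing notes, which give no version of that tool. The annotation and genome build behind the array design are not given in the sources used here. The deposited log2 values were used as they stand, with no further scaling.

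The value table held 35556 probe sets, no missing values and no columns of other samples. A probe set was used for a gene only where the platform annotation pairs it with 1 gene symbol, which was so for 21218 probe sets. Another 1881 had several symbols and 12457 had no name here. This left 18820 genes, of which 1386 had more than 1 probe set and were represented by the one with the highest mean signal. Gene positions relative to Tlr2 came from the RefSeq gene table of assembly GRCm38.p6, which was used for neighbourhood only, so no coordinates are given. Arrays give no read depth, and the number of arrays limits the precision. Array medians lay between 4.37 and 4.56 on the log2 scale.

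Differential expression was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, which moderate each gene's variance using all genes). All 12 arrays entered 1 fit with a mean per group, leaving 8 residual degrees of freedom. The contrasts were methotrexate minus untreated in each genotype, knockout minus wild type in each treatment and averaged over both, and the interaction, which is the methotrexate effect in knockout mice minus that in wild-type mice. Adjusted p-values are Benjamini-Hochberg values over the 18820 genes, and a gene is said to rise or fall where its adjusted p is under 0.05, with no minimum fold. Every value after ± that follows a log2 change is limma's standard error, and values of a group are mean ± SD, always with 3 mice per group. Limma's p-values set a difference between groups against the spread between mice within groups, pooled over the 4 groups. The p-values of camera with the preset correlation and of Fisher's exact test take genes as units, so they are not evidence at the level of mice.

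Before the data were examined, 46 gene lists of cell types, pathways and possible admixed tissues were fixed, and some genes are in more than 1 list. Of these, 44 were tested with limma's camera, which compares the genes of a list with all other genes, using a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 44 lists of a contrast. Camera with the correlation estimated from the data is given beside it as a p. For each list the members called over all genes are counted, beside the members called when p-values were adjusted over the list alone. The lists of sex-linked and erythrocyte genes were not tested, and only genes of the first are described below. The genes named were chosen by a rule also fixed beforehand. It takes the 10 largest rises and the 10 largest falls among called genes whose arrays do not overlap between the groups, leaving out predicted genes. It adds up to 4 members with the smallest p of each list called, and the 5 smallest p-values where fewer than 5 genes are called. It also names 18 genes in every contrast whatever their values, and 2 of these 18 were not analysed here. Genes named outside this rule are marked as chosen after their values were seen.

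The fit and the list test were tested on simulated tables with the real genes' means and variances. For the methotrexate effect in knockout mice, 73 of 100 genes changed by 1 on the log2 scale and 95 of 100 changed by 2 were recovered, with 17 unchanged genes called among the 18820 tested. For the same simulated changes, 42 and 90 of 100 were recovered in the interaction, 76 and 95 between treated genotypes, and 51 and 89 for the genotypes averaged, where the change is diluted by the untreated mice. In 20 simulated tables with no list shifted, camera called 2 lists in all among the 44 tested in each. Only means and variances were taken from the real genes, so these tables cannot show how often camera calls lists of correlated genes wrongly. Correlations estimated from the real data ran from -0.02 for ABC efflux transporters to 0.97 for pancreatic acinar cells. Alternatives tried were a log2 fold minimum of 1, leaving out genes below the 25th percentile of mean signal, the mean of a gene's probe sets, testing all probe sets, quantile normalisation, centring arrays on their median, fitting only the groups compared, the replicate number as a block, a trended robust variance, array weights, and leaving out each of the 12 arrays in turn. Fits that use pancreatic RNA as a block, or only the arrays with or without it, were chosen after seeing the data.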

Results

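The series addressed intestinal mucositis, the injury of the gut lining caused by chemotherapy, and whether it differs in mice without TLR2, a receptor for bacterial lipoproteins. Methotrexate, an antifolate drug that blocks DNA synthesis, was injected intraperitoneally at 40 mg per kg per day for 4 days. The proximal jejunum of the treated mice was taken on day 7. For the untreated mice no injection and no day of sacrifice are recorded. The methotrexate contrasts may therefore also carry effects of injection or of the day of sampling, which were not tested. RNA of 12 mice was profiled, 3 in each of 4 groups: wild type untreated, wild type with methotrexate, knockout untreated and knockout with methotrexate. The labels give the wild type as C57BL6/J and the knockout as B6.129-Tlr2tm1Kir/J. Pearson correlations across all 35556 probe sets between arrays of 1 group were 0.967 to 0.992. Arrays of methotrexate-treated knockout mice correlated at 0.916 to 0.948 with those of the other groups, and the arrays of the other 3 groups at 0.964 to 0.990 with each other across groups. The first principal component held 63.6% of the variance and the second 17.8%.

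The targeted gene was read by 1 probe set. Its signal in untreated mice was 4.37, 4.65 and 4.38 in the arrays labelled wild type and 4.36, 5.02 and 5.01 in those labelled knockout. After methotrexate it was 4.49, 4.65 and 4.51 in wild-type arrays and 6.18, 5.46 and 5.28 in knockout arrays. Tlr2 was thus not lower in the arrays labelled knockout. The position of this probe set relative to the altered part of the gene is not known here, so its signal checks neither genotype nor label, and genotypes are given as labelled. All 12 arrays had high Xist (9.70 to 10.79) and Y-linked Kdm5d between 2.19 and 2.48.

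Genes of the exocrine pancreas were high in 7 of the 12 arrays. The mean over 14 acinar genes was 11.6 to 12.3 in these arrays and 3.94 to 5.40 in the other 5. The 7 arrays were 2 of 3 in the untreated wild type, 2 of 3 in the untreated knockout, 1 of 3 in the treated wild type and 2 of 3 in the treated knockout. Cela3b, a pancreatic elastase, read 2.70, 12.67 and 12.65 in the untreated wild type. Replicate 1 of the untreated wild type also held the highest signal of the fat genes Adipoq (6.50) and Car3 (10.85). Cela3b, Adipoq and Car3 were chosen after their values were seen.

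In wild-type mice, methotrexate was followed by lower expression of 4 of 27 genes of T cells and intraepithelial lymphocytes, a list whose call is lost with an estimated correlation (adjusted p = 0.196). Cd8a, the alpha chain of the CD8 co-receptor, fell by 1.30 ± 0.18 on the log2 scale (adjusted p = 0.0437), and Cd7 fell by 1.74 ± 0.26. The cytotoxic granule gene Nkg7 fell by 1.30 ± 0.19 and the NK receptor gene Klrd1 by -1.18 ± 0.14. The largest fall was that of Lect2, a secreted chemotactic factor, which fell by 2.07 ± 0.27, and Ptges, a prostaglandin E synthase, fell by 0.91 ± 0.13. Acadl, an enzyme of mitochondrial fatty acid oxidation, rose by 1.34 ± 0.19. The other rises were those of Cfhr2 (1.17), Pafah2 (0.99), Gstp3 (0.95), Clca3a1 (0.92), Slc6a7 (0.87), Gramd2 (0.85) and Atp5l (0.68).

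These 14 genes, 8 higher and 6 lower, were all that passed limma's test in wild-type mice, with adjusted p-values from 0.0437 to 0.0499. Unadjusted p-values were under 0.05 for 2198 genes (11.7%), where a share of 0.05 is due with no change at all. Quantile normalisation gave 6 higher and 9 lower genes, and centring the arrays on their median gave 0. Fitting only the 2 groups compared gave 0, and so did the replicate number as a block, while array weights gave 1819. None of the 14 kept its call in all settings run for single genes. Leaving out 1 array gave between 0 and 97 genes, 97 without replicate 1 of the treated knockout, and 0 without any one of replicates 2 and 3 of each untreated group or of the treated wild type. Lct, which encodes lactase, changed by -0.76 ± 0.35 (adjusted p = 0.434) and the crypt gene Olfm4 by -0.05 ± 0.41 (adjusted p = 0.975). The efflux pump genes Abcb1a (0.13) and Abcb1b (-0.02), the gap junction gene Gja1 (-0.21), Tnf (0.10), Il1b (0.02), Mki67 (0.40), Cdkn1a (0.05), Lgr5 (-0.63), Muc2 (-0.11), Tff3 (-0.02), Tlr2 (0.08), Lyz1 (-0.89), Reg3b (0.66) and Reg3g (1.34) did not pass either.

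Among the gene lists, 19 of 44 were called in wild-type mice, 7 higher and 12 lower, and none of the 19 with an estimated correlation, where the smallest adjusted p was 0.0557. Of 27 genes of T cells and intraepithelial lymphocytes, 4 fell over all genes and 13 when adjusted over the list alone, with a median change of -0.70 (camera adjusted p = 3.55e-12; adjusted p = 0.196 with an estimated correlation). Of 22 genes of macrophages and monocytes, 0 were called over all genes and 15 were lower when adjusted over the list alone, median -0.57 (adjusted p = 2.01e-11, and adjusted p = 0.176 with an estimated correlation). The 20 cholesterol biosynthesis genes had 0 calls over all genes and 10 higher when adjusted over the list alone, median 0.51 (adjusted p = 1.66e-10, and adjusted p = 0.263 with an estimated correlation). For the 17 genes of endothelium and lymphatics, 8 were lower when adjusted over the list alone, with 0 over all genes and a median of -0.36 (adjusted p = 1.41e-07, and adjusted p = 0.0557 with an estimated correlation). The 10 Paneth cell genes, which make antimicrobial peptides at the crypt base, had 5 lower when adjusted over the list alone, 0 over all genes and a median of -0.99 (adjusted p = 2.28e-06, and adjusted p = 0.263 with an estimated correlation). Genes of DNA replication (median 0.36), mitosis (0.44), oxidative phosphorylation (0.18) and fatty acid oxidation (0.33) were called higher as lists, with adjusted p from 1.37e-06 to 1.79e-05, but with an estimated correlation their adjusted p was 0.763, 0.763, 0.320 and 0.0914. Without replicate 2 of the treated wild type the medians of DNA replication and mitosis were 0.22 and 0.19, with the call of mitosis lost (adjusted p = 0.121), and that of T cells and intraepithelial lymphocytes was -0.43. Also called were intestinal stem cells (median 0.18) and antimicrobial genes (0.20) as higher, and tuft cells (-0.37), plasma cells (-0.43), eosinophils (-0.20), neutrophils (-0.11), MHC class II (-0.59), enteric neurons and glia (-0.26), pancreatic acinar cells (-2.40) and adipocytes (-0.58) as lower. With an estimated correlation their adjusted p-values lay from 0.158 for tuft cells to 0.797 for pancreatic acinar cells. The pancreatic change goes with the arrays holding pancreatic RNA, 2 of 3 untreated and 1 of 3 treated, and its call is lost with that RNA as a block (adjusted p = 0.763). Some of these calls were lost with 1 array left out. Without replicate 1 of the untreated wild type the adjusted p was 0.428 for stem cells, 0.184 for adipocytes, 0.170 for eosinophils and 0.101 for neutrophils, and the medians of stem cells, adipocytes and eosinophils were 0.04, -0.16 and -0.03. It was 0.171 for antimicrobial genes without replicate 2 of the untreated wild type. Without replicate 3 of the treated wild type it was 0.199 for MHC class II, 0.0516 for enteric neurons and glia and 0.389 for pancreatic acinar cells.

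**Figure D1:**
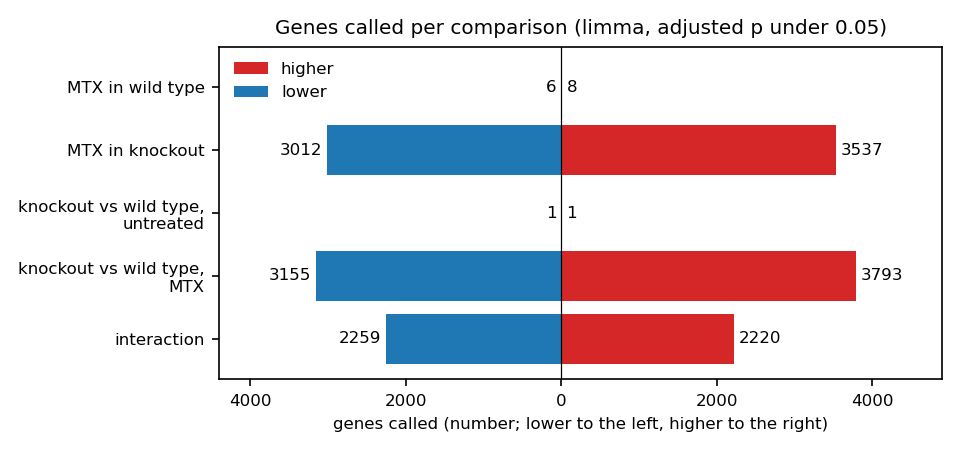
Number of genes called by limma in each comparison, with genes higher to the right of 0 and genes lower to the left. Methotrexate in wild-type mice gave 8 higher and 6 lower genes, and in knockout mice 3537 higher and 3012 lower.

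In knockout mice, methotrexate was followed by lower expression of genes of absorptive enterocytes and higher expression of some antimicrobial and acute-phase genes. The list of enterocyte genes, all 21 of which fell, was called with the preset correlation only (adjusted p = 0.128 with an estimated correlation). The same holds for the antimicrobial and acute-phase list, with 11 of 21 higher and 2 lower (adjusted p = 0.128 with an estimated correlation). Lct fell by 7.81 ± 0.35 on the log2 scale (adjusted p = 4.52e-08), from 11.47 ± 0.35 to 3.66 ± 0.21, and the glucose transporter gene Slc2a2 fell by 6.43 ± 0.45. The trehalase gene Treh fell by 6.06 ± 0.26, and the drug-metabolising cytochrome gene Cyp2b10 fell by 6.60 ± 0.26. Saa3, an acute-phase protein, rose by 6.52 ± 0.48 (adjusted p = 1.39e-06), Lcn2, an iron-sequestering antimicrobial protein, by 5.79 ± 0.21, and Mmp3, a matrix metalloproteinase, by 5.66 ± 0.20. The crypt gene Olfm4 fell by 4.85 ± 0.41 (adjusted p = 3.54e-06).

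Of 18820 genes, 6549 passed limma's test, 3537 higher and 3012 lower, and 2792 of them changed at least 2-fold. Further large falls were those of Sectm1b (-7.15), Ugt2a3 (-6.43), Slc6a20a (-6.32), Naaladl1 (-6.08), Cyp3a25 (-6.00) and the urea cycle gene Otc (-5.96). Further large rises were those of Serpina3n (6.03), Pi15 (5.72), Anxa10 (5.56), the alkaline phosphatase gene Alpl (5.31), Lrg1 (5.23), Cyp1b1 (5.13) and the haptoglobin gene Hp (4.89). The 2 mouse genes for P-glycoprotein, a drug efflux pump, moved in opposite directions: Abcb1a fell by 1.63 ± 0.18 (adjusted p = 3.18e-05) and Abcb1b rose by 2.25 ± 0.14 (adjusted p = 5.03e-07). Gja1, which encodes connexin 43, rose by 2.46 ± 0.12, Tnf by 1.04 ± 0.20, and the antimicrobial lectin genes Reg3b and Reg3g by 2.37 ± 0.42 and 2.12 ± 0.41. Tlr2 rose by 0.85 ± 0.23 (adjusted p = 0.0141), which was lost without replicate 1 of the untreated knockout (adjusted p = 0.0522) and when only the groups compared were fitted (adjusted p = 0.0715). The stem cell gene Lgr5 fell from 6.83 ± 0.31 to 5.84 ± 0.65 (adjusted p = 0.0298), but not when only the groups compared were fitted (adjusted p = 0.0720), nor without replicate 1 or 2 of the untreated knockout (adjusted p = 0.0984 and 0.0590) or replicate 2 or 3 of the treated knockout (adjusted p = 0.0842 and 0.109). The goblet cell gene Tff3 fell by 0.65 ± 0.19 (adjusted p = 0.0200), and its adjusted p was 0.0652, 0.0574 and 0.0541 without replicate 1 of the untreated knockout and replicates 2 and 3 of the treated knockout. Mki67 (0.32), Cdkn1a (-0.18), Lyz1 (-0.03) and Muc2 (0.31) did not pass. Il1b, at 7.62, 4.32 and 4.28 in the treated arrays, did not pass either (adjusted p = 0.252).

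**Figure D2:**
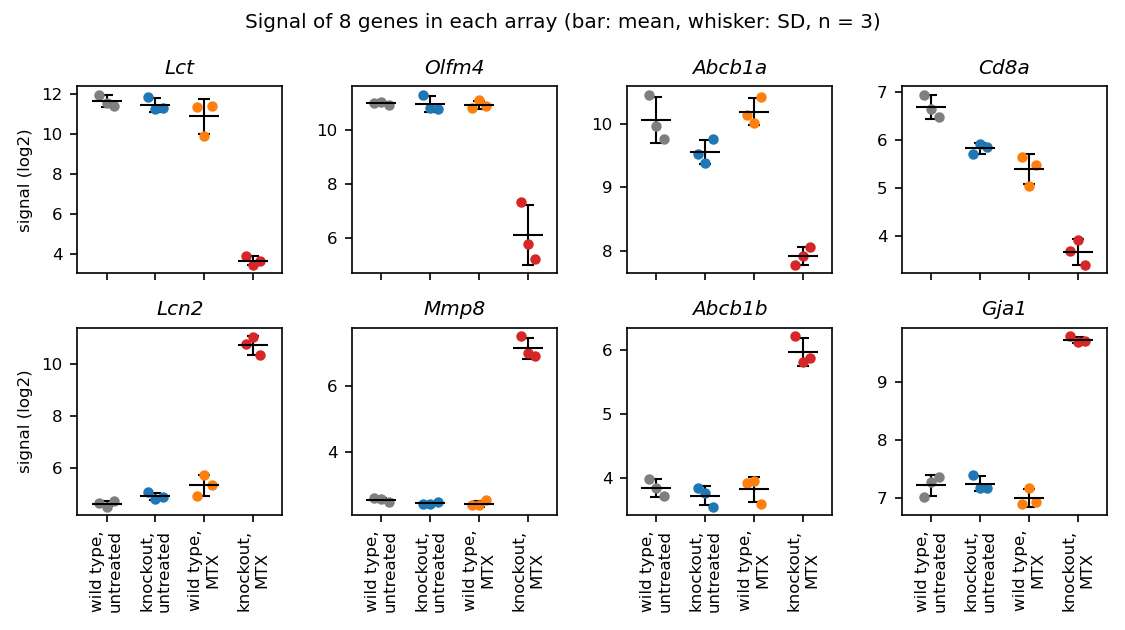
Log2 signal of 8 genes in each of the 12 arrays, 3 per group, where each point is an array and the bar and whisker are mean and SD. Lct was 3.45 to 3.88 in the treated knockout arrays and 9.89 or more in all others, while Lcn2, Abcb1b and Gja1 were higher in the treated knockout arrays than in all others.

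Of the 44 lists, 27 were called in knockout mice after methotrexate, 15 higher and 12 lower. Only that of endothelium and lymphatics was also called with an estimated correlation, and that p is given beside each list. All 21 measured genes of enterocyte digestion and nutrient transport fell, over all genes and when adjusted over the list alone, with a median of -3.65 (camera adjusted p = 4.34e-15; adjusted p = 0.128 with an estimated correlation). Of 32 xenobiotic metabolism genes 27 fell and 1 rose under both adjustments, median -3.33 (adjusted p = 0.112 with an estimated correlation), among them the carboxylesterase gene Ces2a (-5.79) and the glutathione transferase gene Gstm3 (-5.72). In lipid absorption and lipoprotein assembly 20 of 24 genes fell and 1 rose under both adjustments (adjusted p = 0.166 with an estimated correlation), including Mogat2 (-4.09) and Dgat1 (-2.75), which build triglycerides. All 32 genes of oxidative phosphorylation fell under both adjustments, by a smaller median of -0.77 (adjusted p = 0.112 with an estimated correlation), among them the succinate dehydrogenase gene Sdhb (-1.22). Of 20 genes of fatty acid oxidation 12 fell and 3 rose under both adjustments (adjusted p = 0.128 with an estimated correlation), with Ppara at -2.90 and Ehhadh at -2.89. Iron, copper and vitamin handling had 8 of 22 genes lower, and the vitamin D receptor gene Vdr fell by 3.39 ± 0.27 (adjusted p = 0.158 with an estimated correlation). Duodenal and proximal markers had 8 of 14 genes lower, Gata4 by -1.66, and ileal markers 6 of 12, Slc51a by -4.01 (adjusted p = 0.158 and 0.173 with an estimated correlation). Adjusted over the list alone these 3 lists had 8, 8 and 7 genes lower, and the first had 1 higher.

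Stromal and vascular genes rose. Of 27 genes of fibroblasts and extracellular matrix 26 rose and 1 fell under both adjustments, median 2.13 (camera adjusted p = 4.84e-19; adjusted p = 0.103 with an estimated correlation), including the protease inhibitor gene Timp1 (4.69), the collagen gene Col4a1 (2.51) and the Wnt agonist gene Rspo3 (2.24). Of 17 genes of endothelium and lymphatics 15 rose, 16 when adjusted over the list alone, median 1.08 (adjusted p = 1.57e-09, and adjusted p = 0.0270 with an estimated correlation). These include Cdh5 (1.61), which encodes vascular endothelial cadherin. Of 17 genes of enteric neurons and glia 15 rose under both adjustments (adjusted p = 0.130 with an estimated correlation), with Vip at 2.58 and Ednrb at 2.07. Injury-associated epithelial genes had 15 of 25 members higher and 4 lower under both adjustments (adjusted p = 0.128 with an estimated correlation), led by Msln (4.84), Anxa8 (4.03) and Anxa1 (3.72). Smooth muscle genes had 6 of 15 higher and 1 lower under both adjustments (adjusted p = 0.0379, and adjusted p = 0.693 with an estimated correlation), and that call was lost without any one of 4 arrays, with an adjusted p of up to 0.212 without replicate 3 of the untreated knockout, and when dim genes were left out (adjusted p = 0.0988).

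Immune genes moved both ways. Of 22 genes of macrophages and monocytes 18 rose and 1 fell, 19 and 1 when adjusted over the list alone (adjusted p = 0.158 with an estimated correlation). They include the scavenger receptor genes Mrc1 (3.85), Cd163 (3.48) and Msr1 (2.31). Neutrophil genes had 11 of 19 higher under both adjustments (adjusted p = 0.248 with an estimated correlation), with the collagenase gene Mmp8 at 4.70. Their median was 1.66, and 0.71 without replicate 1 of the treated knockout. Inflammatory cytokines and chemokines had 17 of 31 higher under both adjustments (adjusted p = 0.166 with an estimated correlation), including Il11 (2.97), Cxcl2 (2.46) and Il1a (1.96). Antimicrobial and acute-phase genes had 11 of 21 higher and 2 lower, 12 and 2 when adjusted over the list alone (adjusted p = 0.128 with an estimated correlation). Of 31 genes of Toll-like receptor signalling 14 rose and 5 fell, 16 and 6 when adjusted over the list alone (adjusted p = 0.268 with an estimated correlation), with Irak3 at 2.51 and Tlr8 at 2.10. Mast cell genes had 5 of 14 higher under both adjustments, Mcpt1 by 2.40 ± 0.25 (adjusted p = 0.166 with an estimated correlation). T cell and intraepithelial lymphocyte genes had 13 of 27 lower and 2 higher under both adjustments (adjusted p = 0.400 with an estimated correlation), with Gzmb at -2.77 and Cd8a at -2.16. Interferon response genes had 23 of 34 lower and 2 higher, 24 and 3 when adjusted over the list alone (adjusted p = 0.436 with an estimated correlation), with Cmpk2 at -3.40 and Ifit1 at -3.04.

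The p53 target genes had 13 of 31 higher and 4 lower, 15 and 5 when adjusted over the list alone (adjusted p = 0.0160, and adjusted p = 0.456 with an estimated correlation), including Phlda3 (2.73) and Eda2r (1.68). DNA replication genes had 9 of 30 higher under both adjustments, Mcm3 by 1.55 ± 0.31 and Ccne1 by 1.11 ± 0.23 (adjusted p = 0.693 with an estimated correlation), and nucleotide synthesis genes 11 of 28 higher and 2 lower, 13 and 3 when adjusted over the list alone, Rrm2 by 1.73 ± 0.29 (adjusted p = 0.693 with an estimated correlation). Mitosis genes had 3 of 26 higher, and 1 when adjusted over the list alone (adjusted p = 0.763 with an estimated correlation). The calls of these last 3 lists were lost without replicate 1 of the treated knockout, with adjusted p of 0.174, 0.251 and 0.668, and that of mitosis also without replicate 2 or 3 of the untreated knockout (adjusted p = 0.109 and 0.152). Leaving out dim genes also lost the calls of p53 targets, nucleotide synthesis and mitosis (adjusted p = 0.0566, 0.10 and 0.0907). Enteroendocrine genes had 16 of 24 lower and 3 higher under both adjustments (adjusted p = 0.304 with an estimated correlation), with the secretin gene Sct at -1.53. Tight and gap junction genes had 12 of 24 lower and 2 higher under both adjustments (adjusted p = 0.375 with an estimated correlation), with Cldn15 at -2.83 and Ocln at -1.33. Pancreatic acinar genes were not called (median -0.41, adjusted p = 0.827), nor were B cells, plasma cells, eosinophils, MHC class II, adipocytes, goblet cells, Paneth cells, tuft cells, intestinal stem cells, folate metabolism, ABC efflux transporters, cholesterol biosynthesis, ER stress, immediate early genes or the 2 circadian lists.

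**Figure D3:**
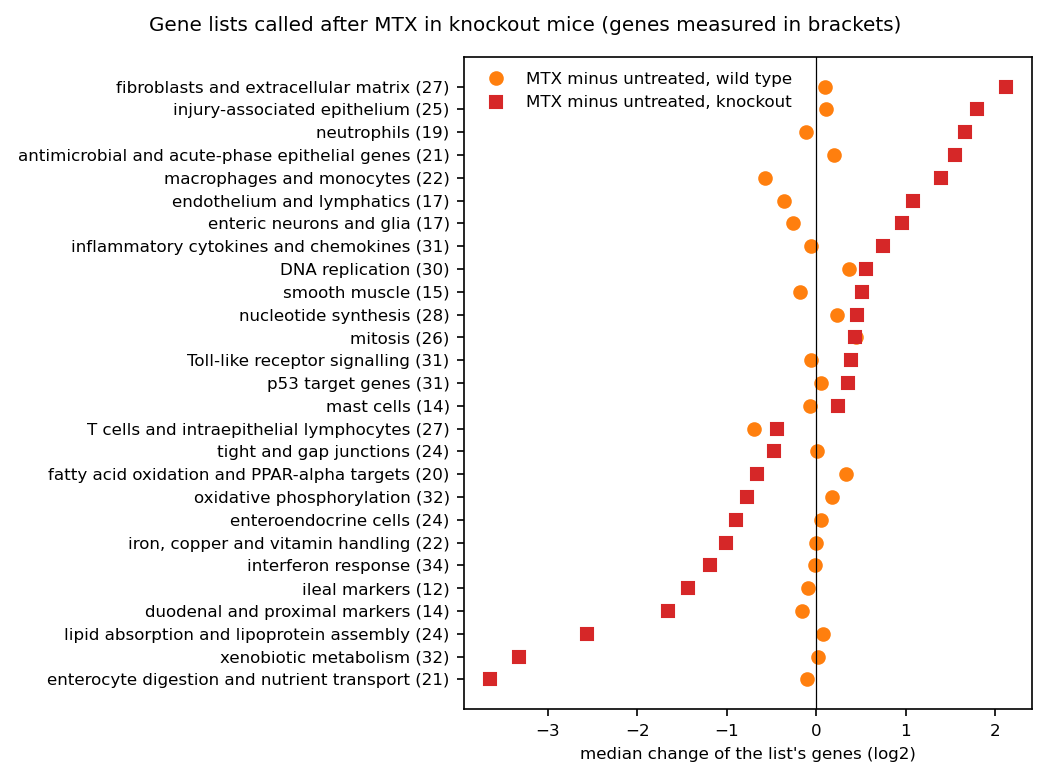
Median log2 change after methotrexate of each of the 27 gene lists called in knockout mice, with wild-type mice as circles and knockout mice as squares. The knockout medians run from -3.65 for enterocyte digestion and nutrient transport to 2.13 for fibroblasts and extracellular matrix, and the wild-type medians of these 2 lists are -0.10 and 0.10.

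The response to methotrexate differed between the genotypes in many enterocyte and stromal genes and in part of the inflammatory genes. In the interaction, Lct was -7.05 ± 0.50 (adjusted p = 3.08e-06), Slc2a2 -6.38 ± 0.64 and Olfm4 -4.80 ± 0.57, each more negative in knockout mice. Saa3 was 6.50 ± 0.68 (adjusted p = 4.59e-05), Mmp3 6.01 ± 0.29 and Lcn2 5.09 ± 0.30, each more positive in knockout mice. Abcb1a (-1.76 ± 0.26) and Abcb1b (2.27 ± 0.20) passed in opposite directions, and Gja1 was 2.67 ± 0.17. In all, 4479 genes passed, 2220 above 0 and 2259 below, and 4254 of them were also called after methotrexate in knockout mice. Tnf passed at 0.95 ± 0.28 (adjusted p = 0.0314), but not with all probe sets tested (adjusted p = 0.0510) or without any 1 of 7 arrays (adjusted p = 0.0538 to 0.0758). These were replicates 2 and 3 of both untreated groups and the 3 of the treated wild type. Among the always-named genes Tlr2 (0.77), Lgr5 (-0.37), Tff3 (-0.63), Mki67 (-0.08), Cdkn1a (-0.23), Muc2 (0.42), Lyz1 (0.86), Reg3b (1.71), Reg3g (0.78) and Il1b (1.09) did not pass.

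Of the 44 lists, 23 were called in the interaction, 12 higher and 11 lower in knockout mice. That of endothelium and lymphatics, with 16 of 17 genes called above 0 over all genes and 17 when adjusted over the list alone, was also called with an estimated correlation (adjusted p = 0.00947). Fibroblast and matrix genes had 26 of 27 called above 0 and 1 below under both adjustments, among them Timp1 at 4.59 and Rspo3 at 2.47 (adjusted p = 0.0578 with an estimated correlation). Macrophage and monocyte genes had 19 of 22 called above 0, and 19 above and 1 below when adjusted over the list alone (adjusted p = 0.109 with an estimated correlation), with Mrc1 at 4.38 and Cd68 at 2.81. Of 21 enterocyte genes, all of them below 0, 19 were called, 20 when adjusted over the list alone (adjusted p = 0.109 with an estimated correlation), and of 32 xenobiotic metabolism genes 28 were called below 0 and 1 above under both adjustments (adjusted p = 0.0578 with an estimated correlation). Of 31 inflammatory cytokines and chemokines 26 lay above 0 and 12 were called so, 13 when adjusted over the list alone (adjusted p = 0.189 with an estimated correlation), and of 19 neutrophil genes 18 lay above 0 and 8 were called so, 10 when adjusted over the list alone (adjusted p = 0.209 with an estimated correlation). The medians of these 2 lists, 0.63 and 1.60, were 0.36 and 0.81 without replicate 1 of the treated knockout. Of 32 oxidative phosphorylation genes, all of them below 0, 29 were called, and 32 when adjusted over the list alone (adjusted p = 0.0578 with an estimated correlation). Cholesterol biosynthesis genes had 6 of 20 called below 0, 8 when adjusted over the list alone, with Tm7sf2 at -1.73 and Dhcr7 at -1.47 (adjusted p = 0.441 with an estimated correlation). The list of T cells and intraepithelial lymphocytes was called lower after methotrexate in each genotype with the preset correlation only (adjusted p = 0.196 in wild-type and 0.400 in knockout mice with an estimated correlation). It was not called in the interaction (median -0.11, adjusted p = 0.583), nor were DNA replication (0.10, adjusted p = 0.489) and mitosis (-0.04, adjusted p = 0.966).

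Across all genes the log2 changes after methotrexate in the 2 genotypes had a Pearson r of 0.098 and a Spearman rho of 0.060, where genes are not independent replicates. Of the genes called in knockout mice, 49.2% had the same sign in wild-type mice, and their median absolute change was 0.89 in knockout and 0.18 in wild-type mice. Of the 14 genes called in wild-type mice, Acadl, Cfhr2 and Clca3a1 rose and Lect2, Cd7, Nkg7, Cd8a and Klrd1 fell in knockout mice too, which is 3 against 1.5 and 5 against 0.960 for independent lists. Gramd2, Gstp3, Pafah2 and Slc6a7 rose in wild-type and fell in knockout mice, and Ptges fell in wild-type mice and rose by 2.30 ± 0.13 in knockout mice. The correlation was -0.007 without replicate 2 of the treated wild type, -0.013 without replicate 1 of the treated knockout, and 0.180 without replicate 1 of the untreated knockout.

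**Figure D4:**
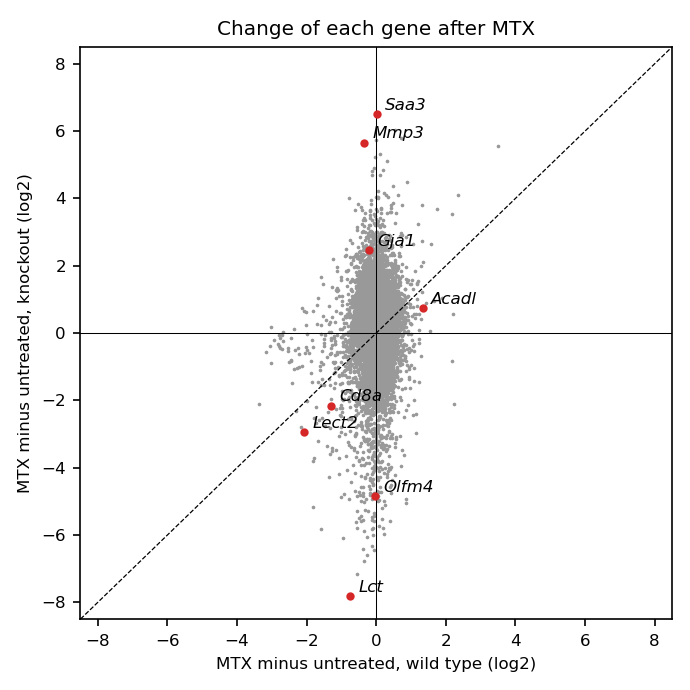
Log2 change after methotrexate of each gene in wild-type mice (horizontal) and knockout mice (vertical), with the dashed line marking equal change. Lct lies at -0.76 and -7.81 and Saa3 at 6.52 on the vertical axis, while Cd8a (-1.30 and -2.16) fell in both.

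In untreated mice the genotypes differed in 2 genes, against 558 with array weights and 78 in only the arrays with pancreatic RNA. Mmrn1, which encodes multimerin 1, a protein of platelets and endothelium, was higher in knockout mice by 2.44 ± 0.15 (adjusted p = 7.01e-05), at 5.45 ± 0.02 against 3.02 ± 0.15. Cyp1a1, an aryl hydrocarbon receptor target that oxidises xenobiotics, was lower by -2.22 ± 0.27 (adjusted p = 0.0425). Entpd4 (0.87 ± 0.11, adjusted p = 0.0565), Churc1 (-1.28 ± 0.18, adjusted p = 0.0917) and Trmt112 (0.53 ± 0.09, adjusted p = 0.221) came next and did not pass. None of the always-named genes passed, with Lct at -0.17, Olfm4 at -0.01, Abcb1a at -0.50, Abcb1b at -0.12, Gja1 at 0.03, Tnf at -0.53 and Tlr2 at 0.32. A total of 1165 genes (6.19%) had an unadjusted limma p under 0.05, where a share of 0.05 is due with no difference at all. The call of Cyp1a1 was lost without any 1 of the 6 untreated arrays (adjusted p = 0.110 to 0.326), without replicate 2 of the treated wild type (adjusted p = 0.0731) or of the treated knockout (adjusted p = 0.110), and when all probe sets were tested (adjusted p = 0.106). Mmrn1 passed in every alternative run for single genes. Neither gene was among those called in the fit of only the arrays without pancreatic RNA, which holds 1 array of each untreated group.

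Of the 44 lists 16 were called between untreated genotypes, 9 higher and 7 lower in knockout mice, and none with an estimated correlation (smallest adjusted p = 0.676). The 27 genes of T cells and intraepithelial lymphocytes had a median of -0.57, with 0 called over all genes and 11 lower when adjusted over the list alone (camera adjusted p = 2.20e-14; adjusted p = 0.676 with an estimated correlation). Xenobiotic metabolism genes had a median of -0.23, with Cyp1a1 lower over all genes and 3 lower when adjusted over the list alone (adjusted p = 1.25e-06, and adjusted p = 0.693 with an estimated correlation). Goblet cell genes had a median of 0.37, and 0.23 without replicate 1 of either untreated group, and 0 calls under both adjustments (adjusted p = 6.68e-05, and adjusted p = 0.759 with an estimated correlation). Macrophage and monocyte genes had a median of -0.20 and 0 calls under both adjustments (adjusted p = 6.68e-05, and adjusted p = 0.693 with an estimated correlation). Most of the other lists called were lost without some array, such as adipocytes without replicate 1 of the untreated wild type (adjusted p = 0.579). The adipocyte median turned from -0.21 to 0.07 without that array.

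After methotrexate, many enterocyte genes were lower and many stromal and some inflammatory genes higher in knockout than in wild-type mice. Lct was lower by -7.22 ± 0.35 (adjusted p = 6.40e-08), the alcohol dehydrogenase gene Adh4 by -6.43 ± 0.30 and the fatty acid transporter gene Slc27a2 by -6.28 ± 0.31. Saa3 was higher by 6.43 ± 0.48 (adjusted p = 1.25e-06), Igfbp5 by 5.08 ± 0.13 and Lcn2 by 5.38 ± 0.21. Mmrn1 was higher by 3.99 ± 0.15 and Cyp1a1 lower by -3.73 ± 0.27, and these were the only 2 genes called in both genotype comparisons. Abcb1a was lower by -2.26 ± 0.18 and Abcb1b higher by 2.15 ± 0.14, Gja1 was higher by 2.70 ± 0.12 and Tlr2 by 1.09 ± 0.23. A total of 6948 genes passed limma's test, 3793 higher and 3155 lower in knockout mice, and 24 of 44 lists were called, 12 in each direction. All 21 enterocyte genes were lower under both adjustments (adjusted p = 0.116 with an estimated correlation), and 26 of 27 fibroblast and matrix genes were higher and 1 lower under both (adjusted p = 0.0541 with an estimated correlation). Of 31 genes of inflammatory cytokines and chemokines 14 were higher under both adjustments (adjusted p = 0.272 with an estimated correlation), with a median of 0.62, and 0.37 without replicate 1 of the treated knockout. All 17 genes of endothelium and lymphatics were higher under both adjustments (adjusted p = 0.0152 with an estimated correlation), the only list called with that setting. Of 10 Paneth cell genes 7 were higher, 8 when adjusted over the list alone (adjusted p = 0.00548, and adjusted p = 0.415 with an estimated correlation), with Pla2g2a at 3.73, Mmp7 at 2.95 and Lyz1 at 0.92. Tnf (0.41), Il1b (1.30), Reg3b (1.17), Reg3g (0.43), Muc2 (0.74), Tff3 (-0.30), Lgr5 (-0.04), Mki67 (0.10) and Cdkn1a (-0.01) did not pass.

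The knockout allele was made in another strain, whose sequence can stay beside the target, so calls near Tlr2 were counted, over the 2 genotype comparisons averaged, in which 5606 genes passed. Within 10 Mb of Tlr2, 65 of 212 genes (30.7%) were called, against 5538 of 18577 genes elsewhere (29.8%), an odds ratio of 1.04 (two-sided Fisher's exact test p = 0.821). Within 5 Mb the odds ratio was 1.24 (two-sided Fisher's exact test p = 0.356). In untreated mice 0 of the 212 genes near Tlr2 were called and 2 elsewhere. The averaged calls mostly carry the difference between the treated groups, so these counts do not exclude an effect of sequence beside Tlr2.

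**Figure D5:**
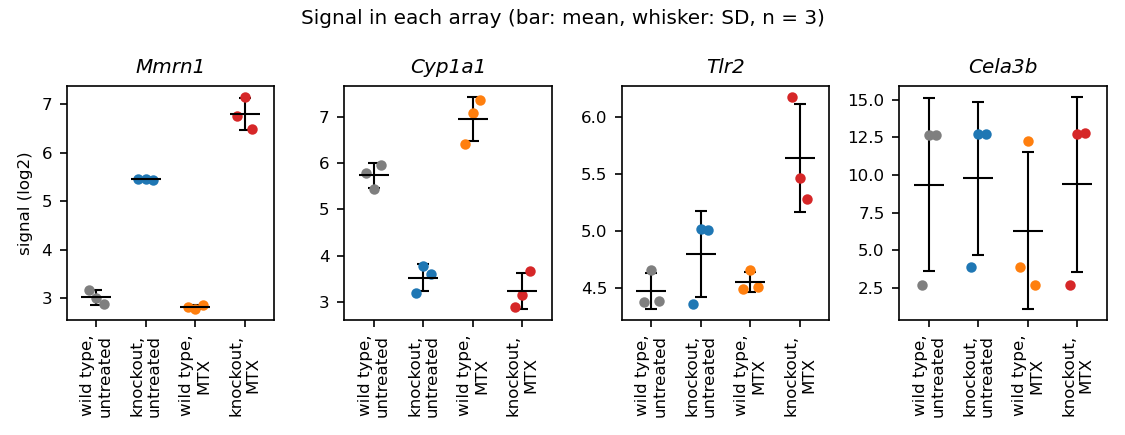
Log2 signal of Mmrn1, Cyp1a1, Tlr2 and the pancreatic gene Cela3b in each of the 12 arrays, 3 per group, where each point is an array and the bar and whisker are mean and SD. Mmrn1 was 3.17 or less in the 6 wild-type arrays and 5.43 or more in the 6 knockout arrays, and Cela3b was high in some arrays of every group.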

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

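The tests of pancreatic RNA and of the epithelial share below were chosen after the result was seen, while that of single arrays and the counts over other splits of the arrays were set beforehand. The response to methotrexate differed between the genotypes by limma's interaction test in 4479 genes. Of the genes named, the interaction was most negative for Lct (-7.05), Sectm1b (-6.59), Slc2a2 (-6.38), Cyp2b10 (-6.33), Otc (-6.19), Slc6a20a (-6.19), Ugt2a3 (-6.04), Rdh7 (-5.98), Slc5a4b (-5.90) and Cyp3a25 (-5.90). It was most positive for Saa3 (6.50), Mmp3 (6.01), Pi15 (5.74), Serpina3n (5.49), Lrg1 (5.27), Alpl (5.21), Lcn2 (5.09), Hp (4.96), Igfbp5 (4.93) and Cyp1b1 (4.83). Olfm4 (-4.80), Abcb1a (-1.76), Abcb1b (2.27), Gja1 (2.67) and Tnf (0.95) differed too, and so did the list of endothelium and lymphatics (adjusted p = 0.00947 with an estimated correlation). Among 14338 probe sets without exactly 1 named gene, which the comparisons leave out, 910 were called in the interaction.

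Many genes were called after methotrexate in knockout mice and few in wild-type mice. With pancreatic RNA as a block, 4370 of the 4479 interaction genes stayed called in the same direction, and with any 1 array left out at least 3778 did, so neither that tissue nor a single array accounts for most of the pattern. A smaller share of epithelium would raise all other cell types alike, but the mean changes of 6 lists of cells outside the epithelium spanned 2.69 in knockout mice. They ran from 2.20 for fibroblasts and extracellular matrix over 0.44 for smooth muscle and 0.07 for B cells to -0.49 for plasma cells. Endothelium and enteric neurons rose by 1.12 and 1.11. The span was 2.94 with T cells and intraepithelial lymphocytes, which is not counted since such cells sit in the epithelium. The lists did not rise alike, so an equal rise through that share was not the only change. List members can also change within cells, and Xbp1 and Edem1 of the plasma cell list are in the ER stress list too. How much of the pattern that share accounts for therefore cannot be told from these lists. A part played by a smaller epithelial share may remain, as may a larger injury or a later recovery in knockout mice at day 7 and any difference between the mice other than TLR2, and the design, with 1 time point, tested none of these. Of 100 splits of the arrays, 8 gave at least 4479 interaction genes (highest other 5713), a share that does not exclude chance. All 8 kept both methotrexate groups whole, and the real split gave the lowest count among them. The other 92 mixed treated arrays of both genotypes, which widens the spread within groups, and gave at most 1 gene. The counts are thus set by the treated groups and do not test the interaction against chance.

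For the comparisons of 3 against 3 arrays only 10 splits exist, too few for a share under 0.05. The real split gave 14 genes for methotrexate in wild-type mice (1 split as large, highest other 0) and 6549 in knockout mice (1 split, highest other 1). It gave 2 genes between untreated genotypes (1 split, highest other 1) and 6948 between treated ones (1 split, highest other 0). For the genotypes averaged over treatments, 1 of 100 splits, the real one, reached 5606 genes (highest other 4832), a share under 0.05. All 8 splits that kept the methotrexate groups whole gave 4479 to 5606 genes and the other 92 at most 1, so the share is set by the treated groups and is not taken to exclude chance.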

How the results depend on the processing

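The settings that use pancreatic RNA were chosen after seeing the data, and the cause of a change was not tested unless the setting itself removes genes or arrays. Single genes were not run with the fold minimum or in only the arrays with or without pancreatic RNA, and lists in fewer settings still. In the settings run, no called named gene changed sign and no called list was called in the opposite direction. Changes of genes that stayed uncalled were not checked for sign. The adipocyte median between untreated genotypes turned from -0.21 to 0.07 without replicate 1 of the untreated wild type, with its call lost. Of the called named genes, 113 of 113 for treated genotypes, 121 of 127 for methotrexate in knockout mice, 103 of 108 in the interaction, 1 of 2 for untreated genotypes and 0 of 14 for methotrexate in wild-type mice kept their call in all settings run for single genes. A log2 fold minimum of 1, which only removes genes, left 7 genes for methotrexate in wild-type mice, 2792 in knockout mice, 3284 between treated genotypes, 2845 in the interaction and 1158 for the genotypes averaged. The 14 genes in wild-type mice became 6 with all probe sets tested, 0 with median centring, 0 with only those 2 groups fitted, 7 with trended robust variance, 1819 with array weights, 34 with pancreatic RNA as a block, 836 in only the arrays with it (1 of them treated wild type) and 8, none among the 14, in only the arrays without it (1 of them untreated wild type). With arms of 1 array these last 2 fits test little. The 2 genes between untreated genotypes became 1 with all probe sets tested, 4 with trended robust variance, 558 with array weights, 78 in only the arrays with pancreatic RNA and 2 other genes, both lower, in only the arrays without it (1 per untreated group). Array weights gave 7474 interaction genes and 8506 for the genotypes averaged. Leaving out 1 array gave 0 to 97 genes for methotrexate in wild-type mice (97 without replicate 1 of the treated knockout, 30 without replicate 1 of the untreated knockout), 5529 to 6637 in knockout mice, 1 to 6 between untreated genotypes (6 without replicate 1 of the treated knockout, 4 without replicate 1 of the untreated knockout), 5852 to 7210 between treated genotypes, 3825 to 5165 in the interaction and 4649 to 6120 for the genotypes averaged. Over all 5 contrasts 109 lists were called, 3 with an estimated correlation and 98 to 116 with 1 array left out. The correlation of the methotrexate changes, 0.098, ranged from -0.013 to 0.180, turning to -0.013 without replicate 1 of the treated knockout and -0.007 without replicate 2 of the treated wild type. The odds ratio near Tlr2, 1.04, was 0.962 to 1.17 with 1 array left out. The labels do not say that replicate numbers pair the mice: same-numbered arrays correlated at -0.486 to 0.671 in their deviations (15 of 18 pairs over 0.1), and 9 of 12 arrays correlated best with their own number. Other-numbered arrays correlated at -0.647 to 0.578 (12 of 36 pairs over 0.1). Pancreatic RNA was absent from replicate 1 and present in replicate 2 of every group, and present in replicate 3 of every group but the treated wild type. That array, replicate 3 of the treated wild type, correlated at -0.486, -0.383 and -0.153 with replicate 3 of the other groups. With replicate 1 of these groups, which lacks that RNA too, it correlated at 0.578, 0.456 and 0.248. Arrays of different groups that both held that RNA correlated at 0.242 to 0.525 with the same number and 0.207 to 0.554 with another. The deviations thus went with pancreatic RNA, and pairing beside it is not excluded. With a replicate block the genes called were 0 and 6455 for methotrexate in wild-type and knockout mice, 2 and 6977 between genotypes, 4486 in the interaction and 5604 for the genotypes averaged.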

Other observations

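The tests of Mmrn1 and of pancreatic tissue below were chosen after the result was seen. The genes in this part other than Mmrn1, Cyp1a1, Entpd4, Churc1, Trmt112 and Olfm4 were chosen after their values were seen. Of 16 ABC efflux transporter genes 5 rose and 8 fell after methotrexate in knockout mice, with the list itself not called (adjusted p = 0.279). Abcc4 and Abcc1, which export methotrexate among other substrates, rose by 2.47 ± 0.19 and 1.71 ± 0.20. Abcc2 and Abcg2, which also export it and sit in the apical membrane of enterocytes, changed by -3.40 ± 0.38 and -2.02 ± 0.15. Of 24 genes of folate metabolism and transport 8 rose and 2 fell, and this list was not called either (adjusted p = 0.176). The intestinal folate importer gene Slc46a1 fell by 3.91 ± 0.41 (adjusted p = 1.89e-05), while the mitochondrial folate enzyme gene Mthfd1l rose by 2.08 ± 0.27, and the reduced folate carrier gene Slc19a1 did not pass (0.13 ± 0.42). None of these genes passed in wild-type mice.

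In knockout mice after methotrexate Pigr, the receptor that carries IgA across the epithelium, fell by 3.80 ± 0.23 (adjusted p = 3.58e-07), and the epithelial chemokine genes Ccl28 and Ccl25, which attract plasma cells and gut lymphocytes, fell by 3.94 ± 0.15 and 3.73 ± 0.23. In wild-type mice they did not pass (0.05, 0.71 and 0.03), and the interaction was called for all 3 (Pigr -3.84, Ccl28 -4.64, Ccl25 -3.77). Of 20 stem cell genes 6 rose and 4 fell, with the list not called (adjusted p = 0.562). Among them Cd44 (2.10 ± 0.19) and Smoc2 (1.88 ± 0.13) rose where Olfm4 fell by 4.85 ± 0.41. Of 18 tuft cell genes 7 fell and 2 rose, with the list not called (adjusted p = 0.0604). Rgs13 and Trpm5 fell by 2.93 ± 0.22 and 2.45 ± 0.26, and Avil rose by 1.56 ± 0.23.

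Mmrn1 and Cyp1a1 differed between the genotypes with and without methotrexate, in all 6 against 6 arrays. Entpd4, Churc1 and Trmt112, which did not pass in untreated mice, also separated all arrays by genotype. Entpd4 was 8.41 or less in wild-type and 9.03 or more in knockout arrays. Churc1 was 8.06 or more and 7.21 or less, and Trmt112 9.14 or less and 9.18 or more. Mmrn1 and Cyp1a1 do not themselves lie in sequence kept beside Tlr2 from the strain of the targeted allele, since 0 of the 2 are on chromosome 3 with Tlr2 (Mmrn1 is on chromosome 6 and Cyp1a1 on chromosome 9). An effect of that sequence on genes elsewhere, or of such sequence kept on other chromosomes, was not tested. Fewer lymphatic vessels in wild-type tissue would lower other lymphatic genes, but their median difference over 5 genes was 0.23 in untreated mice, against 2.44 for Mmrn1. A candidate explanation for Mmrn1 is that the wild-type mice came from a C57BL/6 substrain with a deletion spanning this gene, as is known for C57BL/6JOlaHsd, although the label reads C57BL6/J. The highest wild-type value was 3.17, where array medians over genes were 5.10 to 5.55, and the lowest knockout value was 5.43. These values prompted the explanation, and any other cause of low Mmrn1 in wild-type mice would give them too, so they do not test the deletion. Such a substrain would leave differences between genotypes open to strain as well as TLR2, and an explanation for Cyp1a1 was not tested beyond its chromosome.

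Pancreatic acinar genes were high in 7 arrays and lower in the other 5. Pancreatic tissue taken with the jejunum may be the source, since 9 pancreas genes outside the fixed list had a median difference of 5.56 between these arrays, from 2.03 for Reg1, which the gut also expresses at 10.17 in the arrays without pancreatic RNA, to 8.31 for Gp2, and the arrays did not overlap for all 9. Neither genotype nor methotrexate accounts for it, since all 4 groups held arrays of both kinds. With it in the fit, 499 genes followed it, 401 higher and 98 lower. Duodenal and proximal markers were also higher in the arrays with pancreatic RNA within every group. In untreated mice their mean was 9.45 to 9.54 with that RNA and 7.70 to 7.96 without. Ileal markers went the other way there (6.06 to 6.30 against 6.57 to 6.88), but not in the treated knockout. Whether these arrays also differ in the stretch of gut sampled was not tested.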
